A study of Homo sapiens with 6 samples.

How the data were processed

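RNA sequencing was analysed in 6 libraries of SKOV3 cells, 3 labelled TIPE2 and 3 labelled Vector, grouped by the titles given in the labels. Per the labels' protocols, human TIPE2 cDNA was delivered by a lentivirus, cells were selected with puromycin, total RNA was extracted with TRIzol and libraries followed standard Illumina protocols. The labels do not say whether poly(A) selection or a strand-specific kit was used.

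The authors deposited 1 table per library with 58735 Ensembl gene identifiers and their values in FPKM, per the file headers. The submitters' processing notes name CASAVA 1.7, Bowtie and the genome build mm8. That build is of the mouse, whereas all 58735 identifiers are human and are found in GENCODE release 29 for GRCh38, so coordinates here are those of GENCODE 29 on GRCh38. The build used for alignment is not settled by these sources, and the counter and its treatment of strand and of shared reads are not given in the sources used here. Counts per gene were not given as such. Multiplying each FPKM value by the merged exon length of its gene in GENCODE 29 and by a denominator for its library gave whole fragments for 100% of non-zero values in each library, within a tolerance of 0.01. The denominators, between 96.3% and 103% of the assigned fragments, were equal to median-of-ratios size factors over these 6 libraries times the geometric mean of their assigned fragments. The deposited FPKM values are therefore, from the values themselves, already scaled between the libraries. This scaling assumes that most genes do not change.

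Depth was even. The recovered fragments assigned to genes came to 18583473, 17334006 and 16749306 in TIPE2 1, 2 and 3, and to 16398656, 17375930 and 15983317 in Vector 1, 2 and 3. Fragments without molecular identifiers are not independent molecules, so intervals cover counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom was 6.59 for TIPE2 1 and 2 and between 13.9 and 43.1 for the other pairs. This does not show whether libraries came from separate cultures. Each was counted as 1 replicate, as the labels give it.

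The test was written with a branch for counts and a branch for normalized values, and the unit led to the latter. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with trend and robust empirical Bayes, for 12538 genes with a mean of at least 1 FPKM over the 6 libraries, with no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate changes of low genes, and the median standard error was 0.14. Values are means ± SD over libraries. Of 39 gene lists fixed before the data were examined, 34 had at least 5 tested members and were tested with limma's camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation, and fry, served as alternatives. For each list, genes were also adjusted over the list alone. TNFAIP8L2 was tested in addition with an exact two-sided permutation test, and its ratio of fragment rates was given an exact 95% interval. Python 3.11.15 with scipy 1.17.1 was used to read the tables.

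Genes were named by a rule set before the data were examined. It takes TNFAIP8L2 and its 3 family members whatever their result. It adds the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, which only TNFAIP8L2, GUCY1B1 and PLVAP met. Of each list described it then takes up to 4 members with the smallest p. SCNM1, IL6, SOD2, the tested members of the short marker lists and the genes described only in the closing observations were chosen outside this rule, after their values were seen. The result of 1 list and the values of some list members are not reported here.

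The same steps were tested on data simulated for the comparison of TIPE2 with Vector, with a mean of 12540 genes tested in 10 simulations and 200 genes changed, all drawn from genes with a mean of at least 5 FPKM; recovery of lower genes, GUCY1B1 and PLVAP among them, was not measured. They recovered 80.6% of genes changed 2-fold and 99.2% of those changed 4-fold, all with the right sign, with 11.8 false calls on average. The simulated libraries had no shifts shared by many genes, and 200 changed genes ease the adjustment of p. These shares therefore need not hold for the real libraries. A list of 25 genes shifted by 0.5 on the log2 scale was found in 10 of 10 simulations and 0 of 40 unchanged lists were called, with noise simulated independently between genes, which real lists do not have.

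Alternatives set before the data were examined were the replicate number as a block, each library left out in turn, quantile normalization, no filter, a minimum mean of 5 FPKM, limma without trend and robust settings, a pseudocount of 0.1, an absolute log2 change of at least 1 in addition, centring on the median gene, and the other set tests. Added after seeing the data were limma voom on the recovered fragments (genes with at least 10 on average), rescaling to assigned fragments, protein coding genes only, and library weights from limma's arrayWeights, whose estimation stopped before its tolerance was reached. No library was left out of the comparison.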

Results

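Gene expression was measured by RNA sequencing in SKOV3, an established human ovarian carcinoma cell line, carrying either a lentiviral vector with the TIPE2 coding sequence or the vector without it. TIPE2 is the product of TNFAIP8L2, a cytosolic protein of the TNFAIP8 family that binds phosphoinositides and is known mainly as a brake on inflammatory signalling in immune cells. The 6 libraries fell into 2 groups of 3, called TIPE2 and Vector here and numbered 1 to 3 in each, and the comparison asked which transcripts differ when TIPE2 is expressed. Between 15983317 and 18583473 fragments were assigned to genes per library, and values were deposited as FPKM (fragments scaled by gene length and by library depth). The labels call the libraries biological replicates but do not say whether they came from separate transductions, so p-values measure only the spread between these samples.

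TNFAIP8L2 (ENSG00000163154; GRCh38 chromosome 1, 151156629 to 151159749, plus strand) was close to undetected in the Vector cells and abundant in the TIPE2 cells. Its values were 58.4, 47.2 and 48.8 FPKM in the TIPE2 libraries (51.5 ± 6.09, SD, n = 3) and 0, 0.0476 and 0 FPKM in the Vector libraries. These correspond to 1322, 971 and 959 fragments against 0, 1 and 0, a ratio of rates of 3045 with a 95% exact interval of 546.1 to 120300 that covers counting error only. On the log2(FPKM + 1) scale, which understates the change of a gene near 0, the difference was 5.68 with a standard error of 0.11 (limma, adjusted p = 4.92e-07). Every TIPE2 library lay above every Vector library, and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries can give. The gene overlaps SCNM1, a splicing factor gene on the same strand (chromosome 1, 151156664 to 151170297), so fragments from the shared bases cannot be told apart; SCNM1 itself differed by -0.13 (adjusted p = 0.894). The other members of the family were expressed at low levels and did not pass the test. TNFAIP8 had a mean of 1.62 FPKM in TIPE2 and 2.00 FPKM in Vector cells, TNFAIP8L1 had 2.49 FPKM in both groups, and TNFAIP8L3 had 1.25 FPKM against 1.34 FPKM.

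Beyond the introduced gene, few single transcripts separated the groups. GUCY1B1 (ENSG00000061918; chromosome 4, 155758992 to 155807591), the beta subunit of the soluble guanylate cyclase that senses nitric oxide, rose from 2.25 ± 0.0380 FPKM in Vector to 5.98 ± 0.142 FPKM in TIPE2 cells (SD, n = 3), a log2 change of 1.10 with a standard error of 0.10 (limma, adjusted p = 0.0211). PLVAP (ENSG00000130300; chromosome 19, 17351448 to 17377350), a membrane glycoprotein best known from the diaphragms of endothelial caveolae and fenestrae, fell from 7.14 ± 0.323 FPKM to 2.18 ± 0.476 FPKM, a log2 change of -1.37 with a standard error of 0.13 (limma, adjusted p = 0.0322). All 3 TIPE2 libraries lay on one side of all 3 Vector libraries for both genes. Of 12538 genes tested, 2 were higher in TIPE2 cells, TNFAIP8L2 and GUCY1B1, and 1 was lower, PLVAP. At an unadjusted p under 0.05 there were 751 genes, 378 higher and 373 lower, where 627 would be found by chance. The groups did not overlap for 11.5% of tested genes, where chance gives 10%. The calls of GUCY1B1 and PLVAP depended on the set of libraries and on the settings. With all 6 libraries both were lost with the replicate number as a block (adjusted p of 0.174 and 0.151) and with no filter on low values (0.0755 and 0.253), PLVAP also with a pseudocount of 0.1 (0.0542). GUCY1B1 missed the threshold without TIPE2 1, TIPE2 2, Vector 2 or Vector 3 (adjusted p of 0.174, 0.123, 0.142 and 0.0618), with log2 changes between 1.09 and 1.11. PLVAP missed it in the absence of TIPE2 1, TIPE2 2, Vector 1, Vector 2 or Vector 3 (adjusted p of 0.174, 0.0940, 0.160, 0.202 and 0.0666), with log2 changes between -1.47 and -1.35. Leaving out TIPE2 3 instead gave 8 genes higher and 3 lower.

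**Figure D1:**
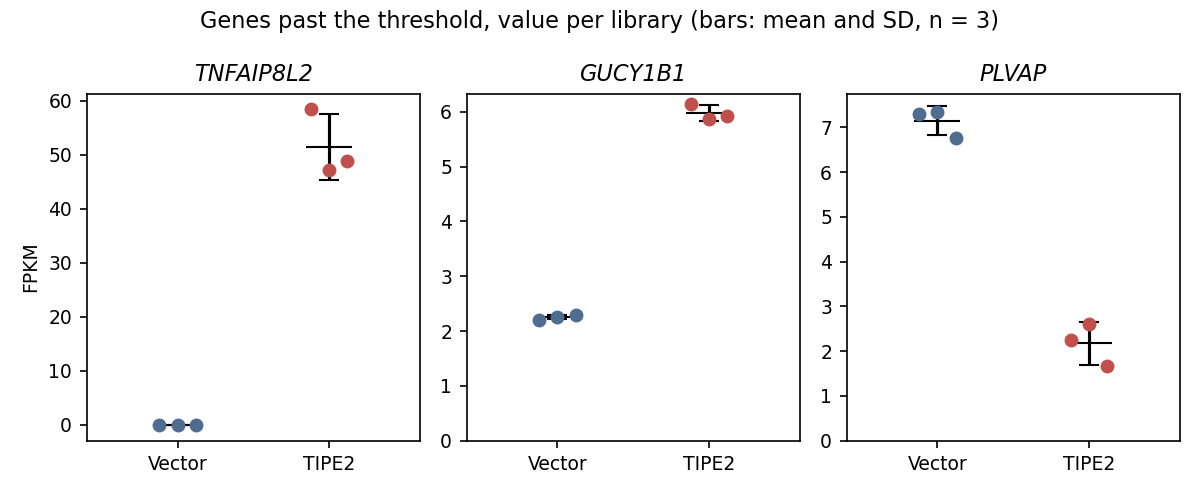
Expression in FPKM (vertical axes, linear, a separate scale per gene) of the 3 genes past the threshold in the Vector and TIPE2 libraries; points are libraries and bars give the mean and SD of 3 libraries. TNFAIP8L2 lies at 47.2 to 58.4 FPKM in TIPE2 and at 0 to 0.0476 FPKM in Vector libraries, GUCY1B1 is higher and PLVAP lower in each TIPE2 library.

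The libraries of a group differed from each other about as much as the groups did. Correlations of log2(FPKM + 1) lay between 0.969 and 0.989 within groups and between 0.960 and 0.985 across them. The first principal component, with 40.2% of the variance, ran from TIPE2 1 to Vector 1 and placed TIPE2 3 beside Vector 3.

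**Figure D2:**
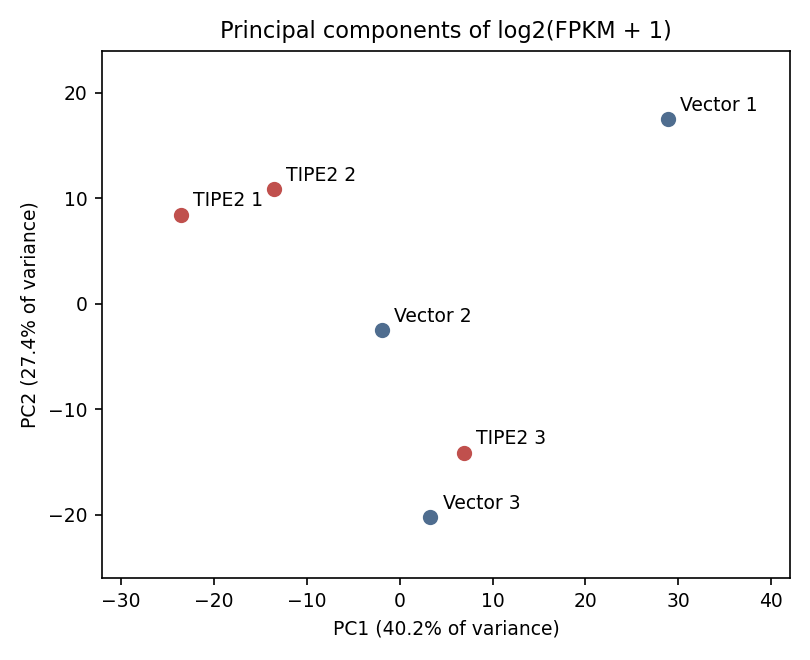
First (horizontal, 40.2% of variance) and second (vertical, 27.4%) principal components of log2(FPKM + 1) in the 6 libraries. TIPE2 1 and TIPE2 2 lie together on the left, Vector 1 lies far to the right, and TIPE2 3 lies closest to Vector 3.

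Gene lists fixed before the data were examined were tested as groups. NF-kB target genes were lower as a group in TIPE2 cells with the preset correlation between genes. Of 21 members tested, 20 had a lower mean in TIPE2 cells, with a median log2 change of -0.73 (limma camera with a preset correlation of 0.01, adjusted p = 1.34e-09). The members moved together from library to library, with an estimated correlation of 0.632, and the group's call was lost with it (adjusted p = 0.644 with an estimated correlation). With no filter on low values, which adds members near the floor, the median was -0.45. None passed over all genes tested, and 4 were lower when adjusted over the list alone. NFKB2, which encodes the p100 precursor of the alternative NF-kB pathway, had 7.54 ± 1.17 FPKM in TIPE2 and 15.0 ± 4.78 FPKM in Vector cells. Its partner RELB had 5.47 ± 0.865 FPKM against 12.6 ± 5.03 FPKM. TNFAIP3, the A20 feedback inhibitor, had 5.05 ± 1.42 FPKM against 12.8 ± 5.77 FPKM, and the inhibitor of apoptosis BIRC3 had 1.18 ± 0.150 FPKM against 3.02 ± 1.34 FPKM (SD, n = 3 throughout). Each of these 4 had an adjusted p of 0.0418 over the list alone and 0.662 over all genes (limma), and was lower in every TIPE2 library than in every Vector library. The mean of the list, relative to the 6 libraries, was -0.59, -0.32 and -0.03 in TIPE2 1, 2 and 3 and 0.59, 0.60 and -0.24 in Vector 1, 2 and 3. Vector 3 thus lay below TIPE2 3. The median was -0.44 without Vector 1 and -1.03 without Vector 3, and the call with the preset correlation held without each library in turn.

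**Figure D3:**
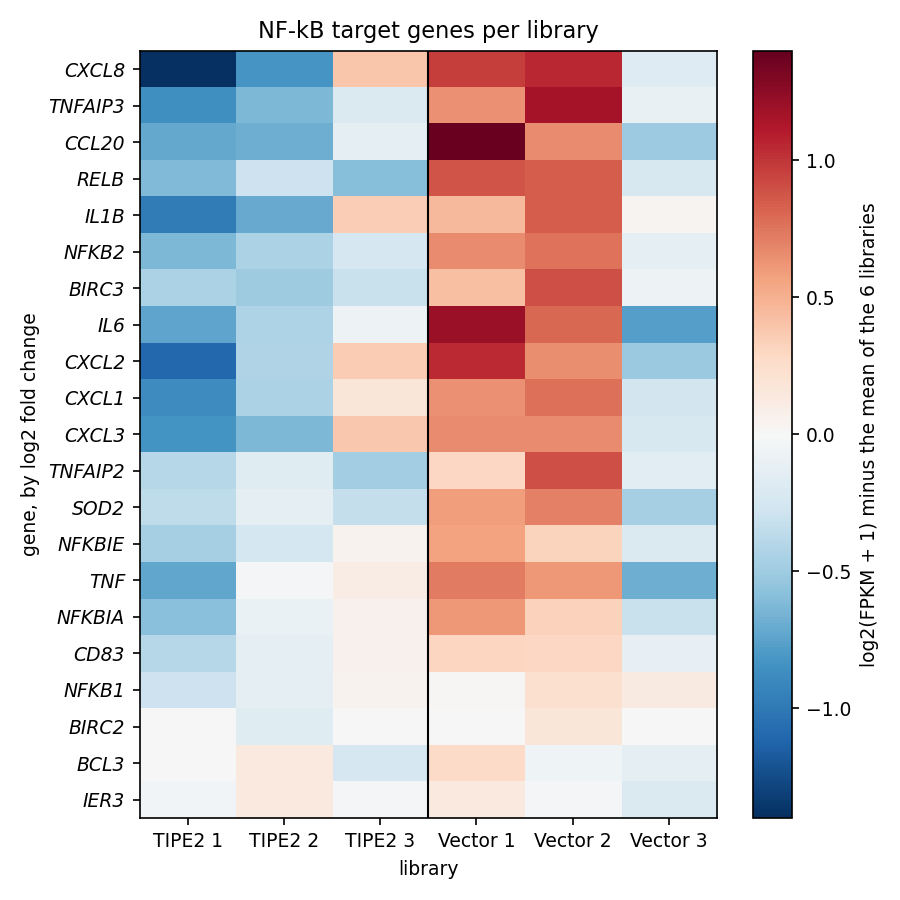
Heat map of the 21 tested NF-kB target genes (rows, ordered by log2 fold change) in the 6 libraries (columns); colour gives log2(FPKM + 1) minus the mean of the 6 libraries. The mean over the list is highest in Vector 1 and Vector 2 (0.59 and 0.60) and lowest in TIPE2 1 (-0.59), with TIPE2 3 and Vector 3 between (-0.03 and -0.24); single genes depart from this order, such as IL6 and SOD2, which are lowest in Vector 3.

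Inflammatory cytokines and chemokines, a list that shares 8 of its 15 tested genes with the NF-kB list, had a median log2 change of -0.77 (13 of 15 members negative, camera adjusted p = 1.36e-04; adjusted p = 0.644 with an estimated correlation). With no filter on low values the median was -0.29. The 7 genes outside the NF-kB list had a median of -0.31, and 5 of them were negative. None of the 15 passed, over all genes or adjusted over the list alone. Leaving out 1 library at a time moved the median of the list between -1.09 (without Vector 3) and -0.46 (without Vector 1), and the call with the preset correlation held each time. The interleukin IL1A had 4.51 ± 3.16 FPKM in TIPE2 and 11.3 ± 1.13 FPKM in Vector cells (adjusted p = 0.0805 over the list alone); without TIPE2 3 it had an adjusted p of 0.0123 over all genes. The macrophage growth factor CSF1 had 31.3 ± 3.79 FPKM against 47.6 ± 11.9 FPKM, and IL1B had 1.21 ± 1.14 FPKM against 2.88 ± 1.09 FPKM. TNFSF10, the death receptor ligand TRAIL, went the other way, with 8.16 ± 3.32 FPKM against 3.81 ± 1.50 FPKM.

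Genes of the G1/S transition and DNA replication were also lower as a group, with 25 of 28 members negative and a median of -0.25 (camera adjusted p = 1.36e-04; adjusted p = 0.744 with an estimated correlation). Without 1 library at a time the median lay between -0.37 and -0.17. The members moved together, with an estimated correlation of 0.517. The mean of the list, relative to the 6 libraries, was -0.27, -0.19 and 0.14 in TIPE2 1, 2 and 3. In Vector 1, 2 and 3 it was 0.18, -0.07 and 0.21, so TIPE2 3 lay above Vector 2. The replication licensing factor CDT1 had 17.4 ± 1.34 FPKM in TIPE2 and 23.4 ± 3.41 FPKM in Vector cells, and the clamp loader subunit RFC3 had 12.2 ± 1.39 FPKM against 15.6 ± 1.59 FPKM. Neither passed, over all genes or over the list alone, and no other member did. Genes of G2/M and mitosis did not pass with all 6 libraries: 19 of 32 were negative, with a median of -0.04 that turned positive with quantile normalization (camera adjusted p = 0.685). The direction rested on single libraries: the median was -0.24 without Vector 3 (adjusted p = 1.56e-05, the 1 such setting that passed), and positive without Vector 1 (0.08), TIPE2 3 (0.04) or Vector 2 (0.001) and with library weights (0.07). CDC20, an activator of the anaphase-promoting complex, had 158 ± 19.1 FPKM against 200 ± 39.3 FPKM, and the checkpoint kinase BUB1B had 27.0 ± 4.13 FPKM against 22.8 ± 3.15 FPKM.

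The lists of hypoxia and glycolysis, of the ATF4 and amino acid response and of oxidative phosphorylation were lower with the preset correlation, none with a member past the threshold over all genes or over the list alone. In the list of hypoxia and glycolysis, 27 of 33 genes were negative, with a median of -0.12 (camera adjusted p = 0.0041; adjusted p = 0.744 with an estimated correlation). Hexokinase HK2 had 4.09 ± 0.721 FPKM in TIPE2 and 5.36 ± 0.294 FPKM in Vector cells, and without Vector 1 the list's call ended (median -0.05, adjusted p = 0.628); without Vector 3 the median was -0.22. In the ATF4 and amino acid response, 17 of 21 were negative with a median of -0.21 (camera adjusted p = 0.00852; adjusted p = 0.744 with an estimated correlation). The mTORC1 inhibitor DDIT4 had 36.9 ± 2.19 FPKM against 53.9 ± 9.88 FPKM, whereas the cystine transporter SLC7A11 had 25.4 ± 4.0 FPKM against 19.4 ± 3.51 FPKM. That call ended without TIPE2 1, TIPE2 2, Vector 1 or Vector 3 (adjusted p of 0.0558, 0.0517, 0.232 and 0.121), and the median lay between -0.35 and -0.13 over the libraries left out in turn. Nuclear genes of oxidative phosphorylation had a median of -0.12, 22 of 27 being negative (camera adjusted p = 0.0274; adjusted p = 0.860 with an estimated correlation), and NDUFB8 of complex I had 2.25 ± 0.485 FPKM against 3.15 ± 0.543 FPKM. Ribosomal protein genes, a further list, were negative in 33 of 39 cases, also with a median of -0.12 (camera adjusted p = 0.0152; adjusted p = 0.860 with an estimated correlation). RPS19 had 207 ± 39.6 FPKM against 248 ± 69.2 FPKM. Vector 1 held the largest share of fragments in ribosomal protein genes, 5.82%, where the other libraries held between 4.10% and 5.31%. Without Vector 1 the ribosomal median turned to 0.03 (adjusted p = 0.271) and the oxidative phosphorylation median was -0.01 (adjusted p = 0.828). Without TIPE2 3 the medians were -0.24 and -0.25. Both calls also ended without TIPE2 1 (adjusted p of 0.657 and 0.601) or TIPE2 2 (adjusted p of 0.0981 each), and with quantile normalization (adjusted p of 0.514 and 0.279).

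Both lists of lipid metabolism were higher with the preset correlation and lost their calls with an estimated one. The estimates, 0.030 for sterol synthesis and 0.073 for fatty acids and phospholipids, were far below the 0.632 of the NF-kB list. In cholesterol and sterol synthesis, 17 of 25 genes were positive with a median of 0.14 (camera adjusted p = 0.0041; adjusted p = 0.644 with an estimated correlation). The sterol methyl oxidase MSMO1, at 20.7 ± 2.11 FPKM in TIPE2 and 13.9 ± 1.08 FPKM in Vector cells, was the 1 member higher when adjusted over the list alone (adjusted p = 0.0454; 0.423 over all genes). The synthase HMGCS1 had 16.4 ± 0.581 FPKM against 12.5 ± 1.71 FPKM. The sterol isomerase EBP had 5.90 ± 0.701 FPKM against 8.20 ± 0.481 FPKM. In fatty acid and phospholipid metabolism, 18 of 27 genes were positive, with a median of 0.13 (camera adjusted p = 0.0214; adjusted p = 0.644 with an estimated correlation). The stearoyl-CoA desaturase SCD had 20.2 ± 0.893 FPKM against 14.3 ± 2.79 FPKM and the phosphatidylinositol transfer protein PITPNB 14.3 ± 1.28 FPKM against 17.1 ± 0.973 FPKM; no member passed. Without TIPE2 3 both calls ended (adjusted p of 0.0538 and 0.0579), and without Vector 1 the second did (median 0.07, adjusted p = 0.232).

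Genes that PI3K-AKT signalling represses through FOXO factors, the arm nearest to the phosphoinositide binding of TIPE2 among the lists, were higher as a group. Of 16 tested, 12 were positive, with a median of 0.22 (camera adjusted p = 0.0041, and 0.644 with an estimated correlation, here 0.023). The call with the preset correlation held without each library in turn. With no filter on low values the median was 0.14. The pseudokinase TRIB1 was higher when adjusted over the list alone, with 16.5 ± 2.08 FPKM in TIPE2 and 10.8 ± 0.756 FPKM in Vector cells (adjusted p = 0.0297; 0.423 over all genes). The pyruvate dehydrogenase kinase PDK4 had 4.06 ± 1.05 FPKM against 2.51 ± 0.481 FPKM, KLF4 had 6.49 ± 0.905 FPKM against 4.86 ± 0.640 FPKM, and the cyclin CCNG2 had 5.26 ± 1.18 FPKM against 3.40 ± 1.07 FPKM.

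All 13 mitochondrially encoded transcripts had a higher mean in TIPE2 cells, with a median of 0.15 (camera adjusted p = 7.26e-04; adjusted p = 0.644 with an estimated correlation). With quantile normalization their adjusted p was 0.0540, and without 1 library at a time the median lay between 0.11 (without Vector 3) and 0.255 (without Vector 1). MT-CYB had 1359 ± 63.1 FPKM against 1068 ± 60.7 FPKM in Vector cells. All 15 genes of MHC class I antigen presentation were positive too, with a median of 0.19 (camera adjusted p = 0.0041, and 0.744 with an estimated correlation). That estimate was 0.62, so the 15 genes moved together. The mean of the list, relative to the 6 libraries, was 0.23, 0.31 and -0.20 in TIPE2 1, 2 and 3. In Vector 1, 2 and 3 it was 0.16, -0.08 and -0.42, so TIPE2 3 lay below Vector 1 and Vector 2. The MHC class I transactivator NLRC5 had 5.02 ± 0.196 FPKM against 4.07 ± 0.712 FPKM, and HLA-C had 203 ± 45.0 FPKM against 161 ± 42.4 FPKM. In the type I interferon response 18 of 25 genes were positive with a median of 0.14 (camera adjusted p = 0.0145; adjusted p = 0.818 with an estimated correlation), and the RNA sensor IFIH1 had 1.63 ± 0.204 FPKM against 1.12 ± 0.192 FPKM. The interferon median was 0.06 with no filter on low values and 0.07 with a mean of at least 5 FPKM. The mean of the interferon list was highest in Vector 1 (0.21), above TIPE2 1, 2 and 3 (0.12, 0.11 and -0.06). In Vector 2 and 3 it was -0.01 and -0.37. No member of these 3 lists passed, over all genes or over the list alone. Without Vector 3 the MHC class I call ended, its median falling to 0.03 (adjusted p = 0.440), and the interferon median turned to -0.02 (adjusted p = 0.868). The MHC class I call also ended without TIPE2 2 (adjusted p = 0.101), and the interferon call without TIPE2 1 (adjusted p = 0.0987). Without Vector 1 the medians were 0.35 and 0.26.

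Among genes of the matrix and of cell identity, collagens and matrix proteins were higher as a group, 16 of 22 being positive with a median of 0.19 (camera adjusted p = 0.0274; adjusted p = 0.860 with an estimated correlation). COL8A1, a short-chain collagen, had 2.55 ± 0.0198 FPKM in TIPE2 and 0.902 ± 0.214 FPKM in Vector cells and was higher when adjusted over the list alone (adjusted p = 0.00187; 0.133 over all genes). Over all genes its adjusted p was 0.0445 among protein coding genes only and 0.0371 by limma voom on recovered fragments. COL6A2 had 58.0 ± 7.08 FPKM against 42.3 ± 3.24 FPKM, and the laminin chain LAMB3 had 63.9 ± 3.87 FPKM against 83.4 ± 3.55 FPKM. TGF-beta and SMAD targets were positive in 13 of 17 cases with a median of 0.17 (camera adjusted p = 0.0274; adjusted p = 0.644 with an estimated correlation), and the inhibitory SMAD7 had 33.2 ± 3.01 FPKM against 22.7 ± 2.39 FPKM (adjusted p = 0.0562 over the list alone). Both calls ended without TIPE2 1 (adjusted p of 0.157 and 0.0917), TIPE2 2 (0.247 and 0.0827) or Vector 3 (0.121 and 0.272), and the collagen call also without Vector 1 (0.918). The size of the collagen difference rested on single libraries, with a median between 0.03 (without TIPE2 2) and 0.46 (without TIPE2 3); that of the TGF-beta list lay between 0.12 and 0.22. Mesenchymal genes did not pass as a list with all 6 libraries (13 of 21 positive, camera adjusted p = 0.131); they did without Vector 2 (adjusted p = 0.0374) and with the replicate number as a block (adjusted p = 0.0365). Of the members, 2 were higher when adjusted over the list alone. SPARC, a collagen-binding matrix protein, had 16.3 ± 4.92 FPKM against 5.72 ± 1.14 FPKM (adjusted p = 0.00959 over the list alone, 0.335 over all genes, and 0.0285 over all genes without TIPE2 3). Fibronectin, FN1, had 82.8 ± 23.4 FPKM against 30.3 ± 10.3 FPKM (adjusted p = 0.0122 over the list alone and 0.355 over all genes). Epithelial markers did not pass as a list either (10 of 17 positive, adjusted p = 0.985). The keratin KRT7 was lower over the list alone (adjusted p = 0.0160; 0.343 over all genes), with 151 ± 13.7 FPKM against 309 ± 71.8 FPKM, and KRT18 had 71.6 ± 4.23 FPKM against 107 ± 24.2 FPKM. The claudin CLDN3 had 8.60 ± 3.17 FPKM against 4.77 ± 1.68 FPKM.

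**Figure D4:**
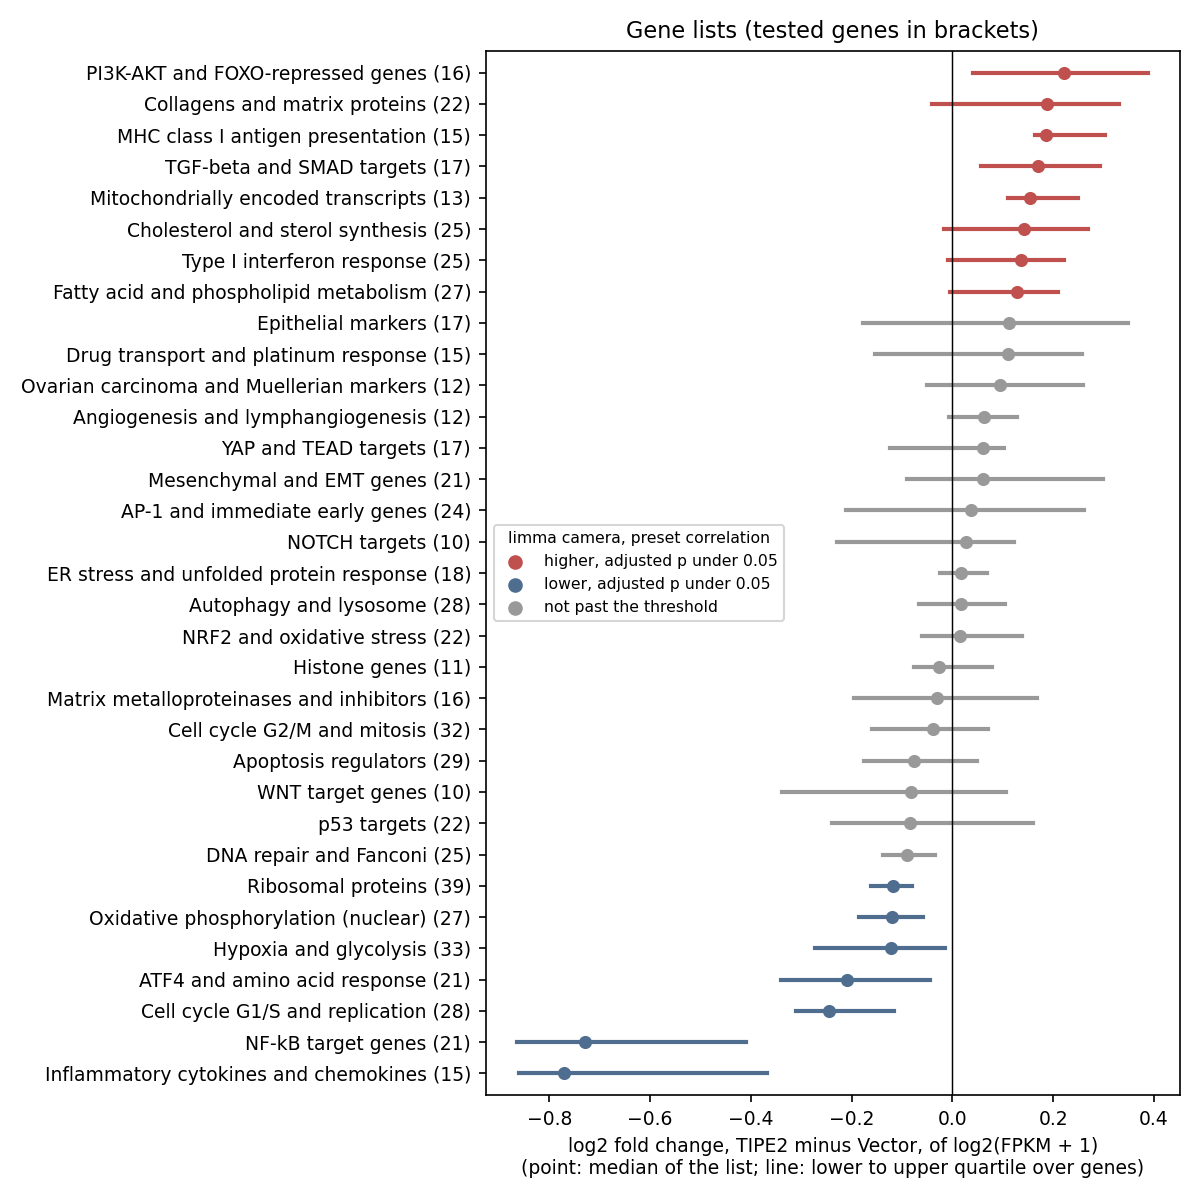
Median log2 fold change (points) and range from lower to upper quartile over genes (lines) of 33 of the 34 gene lists tested, TIPE2 minus Vector on the log2(FPKM + 1) scale; colours mark the 8 lists higher and 7 lower with limma camera and a preset correlation. The inflammatory and NF-kB lists lie lowest, at -0.77 and -0.73 (-0.29 and -0.45 with no filter on low values), and the other medians lie between -0.25 and 0.22.

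Altogether 15 of 34 lists passed with the preset correlation, and with an estimated correlation 0 did. The unadjusted camera p was then under 0.05 for 2 lists, PI3K-AKT and FOXO-repressed genes (0.0356) and sterol synthesis (0.0459). For NF-kB targets it was 0.121. The adjusted p of 0.644 is shared by several lists through the adjustment and does not rank them. By fry, which asks whether a list's genes move one way without comparing them with other genes, 0 passed as well (smallest adjusted p = 0.273). The unadjusted fry p was under 0.05 for 4 lists. It was 0.0112 for DNA repair, 0.0182 for sterol synthesis, 0.0241 for PI3K-AKT and FOXO-repressed genes and 0.0402 for mitochondrially encoded transcripts. For NF-kB targets the unadjusted fry p was 0.115. Fry's test for changes in either direction also gave 0. Other programmes linked to TIPE2 in other cells did not pass even with the preset correlation, with all 6 libraries and the main filter. Apoptosis regulators were balanced, 14 positive and 15 negative (camera adjusted p = 0.554); the anti-apoptotic BCL2L1 had 36.1 ± 4.66 FPKM in TIPE2 and 48.9 ± 5.02 FPKM in Vector cells, and the caspase CASP10 had 1.55 ± 0.218 FPKM against 0.997 ± 0.221 FPKM. AP-1 and immediate early genes were split, 14 positive and 10 negative (adjusted p = 0.685). Within them EGR1 had 519 ± 132 FPKM against 297 ± 22.6 FPKM and FOSB 73.0 ± 7.10 FPKM against 46.2 ± 13.4 FPKM, whereas the ERK phosphatase DUSP5 had 31.7 ± 1.705 FPKM against 43.5 ± 5.29 FPKM. Matrix metalloproteinases and their inhibitors were balanced, 8 and 8 (adjusted p = 0.752), with the urokinase PLAU at 26.1 ± 2.53 FPKM against 37.7 ± 9.75 FPKM and MMP2 at 33.3 ± 7.22 FPKM against 23.9 ± 4.16 FPKM. WNT targets had 6 of 10 members negative (adjusted p = 0.225) and passed with a mean of at least 5 FPKM (median -0.22, camera adjusted p = 0.0211). Among them the WNT antagonist DKK1 had 10.8 ± 10.0 FPKM against 30.4 ± 5.75 FPKM, a difference with an adjusted p of 0.729 over all genes and of 0.0127 without TIPE2 3. CCND1 had 41.1 ± 3.40 FPKM against 60.6 ± 14.8 FPKM and MYC 26.0 ± 2.18 FPKM against 34.1 ± 4.69 FPKM.

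The remaining lists described did not pass with all 6 libraries and the settings used here. Their adjusted p with the preset correlation was 0.0580 for DNA repair (22 of 25 negative), 0.347 for ovarian carcinoma markers and for drug transport, 0.366 for NRF2 targets, 0.554 for autophagy, 0.641 for angiogenesis, 0.685 for p53 targets, 0.705 for the unfolded protein response, 0.917 for NOTCH targets, 0.968 for histones and 0.985 for YAP targets. Some passed under other settings. DNA repair did so with quantile normalization (0.0228), by limma voom on recovered fragments (0.0307), among protein coding genes only (0.0466), with a pseudocount of 0.1 (0.0498) and without TIPE2 1 (0.0341) or Vector 1 (0.0285), each time lower in TIPE2 cells. Without Vector 1, NRF2 targets (0.0037) and autophagy (0.0440) were higher, and ovarian carcinoma markers were higher without TIPE2 3 (0.0156) and with library weights (0.00632). Members with the smallest p included the ovarian surface antigen MSLN, with 9.80 ± 2.89 FPKM in TIPE2 and 17.1 ± 5.90 FPKM in Vector cells, the oestrogen receptor ESR1, with 3.41 ± 1.08 FPKM against 2.09 ± 0.324 FPKM, the autophagy kinase ULK1, with 12.3 ± 0.717 FPKM against 9.61 ± 0.797 FPKM, and the YAP regulator AMOTL2, with 21.9 ± 1.87 FPKM against 15.4 ± 1.64 FPKM. Of the drug transport list, with 9 of 15 members positive, the glutathione transferase GSTA4 had 1.93 ± 0.154 FPKM against 1.14 ± 0.262 FPKM, the copper transporter SLC31A1, which is linked to cisplatin uptake, 8.46 ± 0.392 FPKM against 10.2 ± 0.315 FPKM, and the efflux pump ABCC4 6.94 ± 0.823 FPKM against 5.16 ± 1.08 FPKM.

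Most markers of other cell types were below the filter of 1 FPKM. Of 20 leukocyte markers 1 was tested, CORO1A, with 1.13 ± 0.256 FPKM in TIPE2 and 1.38 ± 0.542 FPKM in Vector cells, and the median over the list was 0.0201 FPKM. Of 10 endothelial markers 1 was tested, EGFL7, with 20.8 ± 2.27 FPKM against 24.7 ± 9.43 FPKM, and the median was 0.0679 FPKM. Of 14 fibroblast and mesothelial markers 2 were tested, COL1A1 (2.23 ± 1.36 FPKM against 0.847 ± 0.610 FPKM) and UPK3B (6.40 ± 2.43 FPKM against 4.93 ± 1.12 FPKM). Of 17 markers of liver, blood, germ and neural lines 1 was tested, POU5F1, with 3.34 ± 0.656 FPKM against 4.60 ± 0.840 FPKM. These lists held too few tested genes for a group test with the filter, and none of the named genes passed. With no filter none of the lists passed (camera adjusted p of 0.787 for endothelial and for leukocyte markers, 0.292 for fibroblast and mesothelial markers and 0.742 for the other lines), nor did the fibroblast and mesothelial list by limma voom (adjusted p = 0.139).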

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

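The alternatives on recovered fragments, rescaled totals, protein coding genes and library weights were chosen after seeing the data. The higher level of TNFAIP8L2 passed under every alternative run, with log2 changes between 5.58 and 10.4, the last by limma voom on recovered fragments, which has no pseudocount of 1. The counts of genes, 2 higher and 1 lower, came to 1 higher (TNFAIP8L2) and 0 lower with the replicate block, with no filter and with a mean of at least 5 FPKM; the last filter leaves out GUCY1B1 and PLVAP by construction, and the cause was not tested for the others. A pseudocount of 0.1 gave 0 lower. Protein coding genes only gave 4 higher and 2 lower, with fewer genes tested, and library weights gave 208 higher and 192 lower. Leaving out 1 library at a time gave between 1 and 8 genes higher and between 0 and 3 lower (limma; between 390 and 1575 genes at an unadjusted p under 0.05). Quantile normalization, limma without trend and robust settings, centring, the fold threshold and rescaled totals kept the same 3 genes, and voom called these 3 and COL8A1.

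The count of 15 gene lists became 0 with an estimated correlation, 0 by fry and 0 where a list's median also had to reach 1 on the log2 scale. Library weights gave 10 lists, with medians of 0.40 for the MHC class I, 0.30 for the mitochondrial and 0.26 for the interferon list. With weights the calls of the ATF4, collagen, fatty acid, hypoxia, oxidative phosphorylation and ribosomal lists ended (camera adjusted p between 0.0714 and 0.433). Leaving out 1 library gave between 9 and 16 lists. With no filter the interferon list missed the threshold (adjusted p = 0.103), and with a mean of at least 5 FPKM it did so too, with the collagen and oxidative phosphorylation lists (0.265, 0.0580 and 0.111). DNA repair passed with no filter (0.0113), and WNT targets with the stricter one (0.0211). Those first 3 settings use the same fold changes, so the medians of the NF-kB list (-0.73) and the inflammatory list (-0.77) could not move; their calls were lost, with adjusted p of 0.644 each for the estimated correlation and of 0.441 and 0.452 by fry. For the first of these losses the estimated correlations between members, 0.632 and 0.346, took the place of the preset 0.01. The unadjusted camera p also rose for some lists with an estimate below 0.01. It went from 0.0654 to 0.135 for the mesenchymal list (estimate 0.00825) and from 0.0273 to 0.0699 for DNA repair (estimate -0.0187). For p53 targets, with an estimate of -0.0247, it did not rise (0.564 to 0.560). For PI3K-AKT and FOXO-repressed genes, with an estimate of only 0.023, it rose from 7.25e-04 to 0.0356. A higher correlation cannot account for the rises of the mesenchymal and DNA repair lists. The correlation therefore need not be the only source of that loss.

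Whether the replicate numbers pair the libraries could not be settled from 3 pairs. Deviations of same-numbered libraries correlated at -0.23, 0.15 and 0.19, and 2 of 3 TIPE2 libraries correlated best with the Vector library of their own number. With the replicate block 1 gene was higher and 0 lower (limma; 719 genes at an unadjusted p under 0.05), and 16 lists passed, the same 15 and the mesenchymal list (adjusted p = 0.0365).

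Of 3051 comparisons for 172 other genes named or eligible, 2962 kept their direction and side of the threshold, nearly all of them without a call in either setting. A call was lost in 14 (GUCY1B1 and PLVAP) and gained in 58. Outside library weights, gains were confined to COL8A1, NMUR2, IL1A, SPARC and DKK1. For IL1A, SPARC and DKK1 the only such setting was the omission of TIPE2 3, and leaving out any other library gave no call. The sign changed in 17, all without a call on either side. TNFAIP8L1 was at -0.031 with quantile normalization. With library weights H2BC12 was at 0.091, HES4 at 0.10, CORO1A at 0.060, EGFL7 at 0.14 and SCNM1 at 0.0051. Over the libraries left out in turn, TNFAIP8L1 ranged from -0.088 to 0.095, TNFAIP8L3 from -0.23 to 0.040, SCNM1 from -0.32 to 0.056, H2BC5 from -0.023 to 0.30, BIRC5 from -0.50 to 0.0037, SEL1L from -0.016 to 0.27, H2BC12 from -0.45 to 0.11, CORO1A from -0.26 to 0.031 and EGFL7 from -0.36 to 0.10; the cause was not tested. Low genes rest on few fragments: the chemokine CCL20 had 10, 10 and 26 in the TIPE2 and 118, 70 and 14 in the Vector libraries. The spread within Vector is larger than counting error.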

Other observations

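Some of the protein coding genes with the smallest p outside the fixed lists are given here; they were chosen after their values were seen, and none passed over all genes. Higher in every TIPE2 library than in every Vector library were the teneurin TENM3 (5.74 ± 0.224 FPKM against 2.54 ± 0.496 FPKM, SD, n = 3, limma adjusted p = 0.136), the guanine nucleotide exchange factor VAV3 (9.54 ± 2.35 FPKM against 4.26 ± 0.797 FPKM), the cytokine signalling inhibitor SOCS3 (27.9 ± 4.09 FPKM against 15.4 ± 2.46 FPKM), the kinase RIPK4 (41.3 ± 2.14 FPKM against 27.5 ± 1.56 FPKM) and the interleukin 1 receptor IL1R1 (7.81 ± 1.41 FPKM against 4.39 ± 0.562 FPKM). Lower in every TIPE2 library were the neuromedin receptor NMUR2 (4.36 ± 0.0377 FPKM against 9.23 ± 1.17 FPKM, adjusted p = 0.118; 0.0445 among protein coding genes only and 0.0446 without Vector 1), the tight junction protein CLDN1 (10.7 ± 0.815 FPKM against 24.5 ± 4.53 FPKM, adjusted p = 0.133), the protocadherin PCDH1 (3.58 ± 0.405 FPKM against 7.01 ± 0.754 FPKM), the forkhead factor FOXQ1 (8.17 ± 0.228 FPKM against 13.2 ± 1.12 FPKM), the EGR1 corepressor NAB2 (13.6 ± 1.75 FPKM against 24.5 ± 2.98 FPKM), the stathmin STMN3 (10.3 ± 3.84 FPKM against 29.7 ± 6.71 FPKM) and the serpin SERPINB5 (9.77 ± 1.74 FPKM against 20.3 ± 4.89 FPKM).

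Of the RNA of the signal recognition particle, chosen after its values were seen, neither RN7SL2 nor RN7SL3 passed. RN7SL2 had 140, 389 and 379 FPKM in TIPE2 and 1126, 1114 and 626 FPKM in Vector libraries, and RN7SL3 had 4.89 ± 1.29 FPKM against 19.1 ± 6.90 FPKM (limma adjusted p of 0.588 and 0.271). Reads of such near-identical copies can be hard to assign, and the treatment of shared reads is not given, so the values of each are uncertain.

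The tests of single libraries, of a library state and of splits of the NF-kB list were chosen after the result was seen; those of weights and of gene length address results already seen, but were set before their own values were. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 3 genes and the highest of the other splits gave 1. As many as in the real split were given by 1 of the 10 splits. TNFAIP8L2 is among the 3 genes and was introduced into the TIPE2 cells by design, so its call says nothing about chance. For gene lists the real split gave 15, and 1 of the 10 splits gave as many. Every other split also gave lists with the preset correlation, between 4 and 12. The preset test thus called lists for any grouping of these libraries, which limits what the 15 calls can show.

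Whether the lower NF-kB targets in TIPE2 cells rest on Vector 1 stays open. Without it the median was -0.44, but the difference in the list's mean, -0.49, had a standard error of 0.37 between the 5 libraries left. The values also leave room for a state of the cultures that varied between libraries apart from TIPE2. The range of the list's mean within the Vector group, 0.84, was 1.33 times the difference between the groups, 0.63. The list passed in 3 of the 9 other splits, and 3 of the 10 splits, the real one included, gave an adjusted p as small as 1.34e-09; TIPE2 1, TIPE2 2 and Vector 3 against the rest gave 2.60e-16, and TIPE2 1, TIPE2 3 and Vector 3 against the rest gave 2.94e-10. The design compares TIPE2 with Vector, so an effect of TIPE2 stays open beside such a state; these libraries do not test one apart from the other.

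Library weights raised the count of changed genes from 3 to 400, and such rises were not particular to the real split. With weights, 3 of the 9 other splits called 3926, 1674 and 461 genes where each called 0 without them; these 3 reached at least 10 times the count without weights, a count of 0 being taken as 1. With the real one, 4 of the 10 splits gave at least 400. Weights were estimated around each split, from 0.220 for Vector 1 to 8.27 for TIPE2 2 in the real one. The counts of 3926 and 1674, several times the real one, could reflect a structure of the samples or the weighting itself, which were not told apart. The 400 genes could likewise be a product of the weighting, and no biological explanation was tested for them.

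The lower ribosomal protein and oxidative phosphorylation lists could come from gene length or from Vector 1. Removing the trend of fold change on gene length moved the ribosomal median from -0.12 to -0.087 (SD over genes 0.081) and the oxidative phosphorylation median from -0.12 to -0.077. The length was that of the merged exons of a gene, not of the transcripts expressed, and the SD is over genes rather than libraries. The test therefore cannot decide how much of either difference comes from length. Without Vector 1 the ribosomal median was 0.030, so the direction of that list rested on this library. An effect of TIPE2 on these genes was not tested apart from it.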
